A study of Andropogon gerardi with 32 samples.

How the data were processed

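Leaf RNA of big bluestem (Andropogon gerardii), a perennial prairie grass, was measured on spotted microarrays in 32 samples, 16 from plants or plots under ambient rainfall and 16 under altered rainfall. The groups were taken from the sample titles. The labels say that rainfall was altered and do not say how, and they give no dye, scanner, background correction or array layout.

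The deposited values are spot intensities on a linear scale, as the authors placed them in the series table, with 1 column per sample and 10447 probes. How the authors made the intensities is not given in the sources used here. The values themselves show 3 things about that processing. Each title carries a number that occurs once under ambient and once under altered rainfall, and for all 16 numbers the ambient and altered columns lack a value at exactly the same spots. The 2 samples of a number were therefore treated as the 2 channels of 1 array. In the deposited intensities 1 channel of an array holds whole numbers (to within 1e-06) and the other holds multiples of a factor, so that the altered channel was multiplied on 11 arrays, the ambient channel on 4 and neither on 1 (number 7). Sample medians ran from 4.25 to 8.62 on the log2 scale, so this scaling had not made the medians of the samples equal. Whether local background had been subtracted is unknown, and no background flag accompanies a spot, so the limit below which a spot holds no signal is unknown too.

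Intensities at 0 (1509 of 194148 values, 0.777%) were set missing and the rest were taken as log2. The plan written before the data were examined kept the values as deposited where sample medians lay within 0.1, and otherwise called for quantile normalization between samples, which was applied. Probes with a value in at least 8 samples of each group were tested, which left 6384 probes. Altered was compared with ambient rainfall in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. All changes are altered minus ambient on the log2 scale, with the standard error (SE) of the fit, and group values are means ± SD of normalized log2 intensities. Adjusted p-values in the text come from this fit unless another is named. The number of arrays limits the precision, as does the number of spots with a value, which ran from 1833 (number 7) to 9530 (number 2).

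The planned fit had no block. A fit with the title number as a block was run beside it. Samples of 1 number mostly did not deviate in the same direction from their group means: the correlation of their deviations ran from -0.25 to 0.36 and was above 0.1 for 2 of 16 numbers. The size of the deviations was shared, however. Over the 894 probes with a value above 0 in all samples, the root mean square deviations of the 2 samples of a number correlated at r = 0.81 (0.44 with median centring). The pairing rests on the identical missing spots, and the result with the replicate block is given where it changes a call. Within-array loess log ratios (span 0.4), the usual treatment of 2-channel arrays, were added after the data were seen. They were tested against 0 over the 16 arrays.

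The sample descriptions have 3 wordings, which follow the numbers 2 to 6 (4 arrays), 7 to 10 (4 arrays) and 11 to 19 (8 arrays). They were treated as possible batches, with fits within each set, a covariate and a moderated F-test of the interaction between rainfall and set. The spread between samples was compared by a permutation test (100000 resamples, two-sided) on each sample's root mean square deviation from its group mean, over the 894 probes with a value above 0 in all samples. An exact test that exchanged samples only within arrays was added after the data were seen. A fit without normalization was also tried, on the deposited values, in which a channel of most arrays had already been multiplied by a factor. Other settings tried were median centring, filters on missing and dim spots, log2(value + 1) and a floor at the 5th percentile. Further settings were sample weights, moderation with a trend, and leaving out each number.

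Gene names came from the platform annotation, which paired 728 of the probes with 1 gene symbol each (506 symbols) and left 9719 unnamed here. The symbols follow the naming of maize genes, so the probes were probably designed from maize, though the sources used here do not name their species. A gene symbol in the text therefore gives the annotation of a probe. Whether the spot measured the matching transcript of big bluestem was not tested. Only 38 of the symbols were other than a locus number, and no description of gene function was given. No symbol could be updated with the sources used here. Probes named in the text are the 12 with the largest rise and the 12 with the largest fall among named probes past the threshold, and up to 3 members of each gene list. The 15 gene lists fixed in advance matched 2 symbols in all (Cab-m7 for light harvesting and hsp70-4 for heat shock proteins). The other 13 lists (C4 and Calvin cycle, dehydration and abscisic acid, reactive oxygen scavenging, aquaporins, ribosomal proteins and translation factors, defence, phenylpropanoid and cell wall, sucrose and starch, chromatin and cell cycle, proteolysis and senescence, transcription factors, mitochondrial respiration, and markers of seed, pollen and root) matched none. The lists were searched mainly by words of gene descriptions, which the annotation lacks. An unmatched list therefore does not mean that its genes were absent, and the tubulin gene tua4, for example, was tested. No list reached the 5 members set as the minimum for a list test, so none was run. Genes with a symbol other than a locus number are also given, a choice made after the annotation was seen.

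The fits were tested on simulated data with the means, spreads and missing spots of the 6384 probes and 100 probes changed by each of 2 sizes. For altered against ambient the main fit recovered 23% of changes of 1 log2 unit and 81% of changes of 2, with 2 false calls among 106. The replicate block recovered 23% and 80%, and the loess log ratios 21% and 77%. For the interaction, run on 5782 probes, 85.9% of simulated differences of 4 log2 units confined to the set of 8 arrays were recovered, with 13 false calls. The simulated noise was independent between samples, with the same spread in all samples for a given probe. It held no array pairing, no intensity-dependent channel effect and no samples of unequal quality. These rates may therefore not hold for the real arrays.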

Results

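Leaf expression was measured in 32 samples of big bluestem, 16 under ambient and 16 under altered rainfall, on 16 two-channel arrays that each held 1 sample of either group. The number of spots with a value differed widely between arrays, from 1833 for number 7 and 2323 for number 19 to 9530 for number 2. Values in the 2 channels of an array correlated at r = 0.76 across probes for number 13 and at r = 0.05 for number 9, and number 7 gave r = -0.31. The labels do not state whether samples of 1 group came from separate plants or plots in every case, so p-values measure the spread between these samples.

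The comparison of altered with ambient rainfall asks which leaf transcripts differ in plants grown under a changed rainfall regime. Of 6384 probes tested, 576 passed the threshold (9.02%), 258 of them higher and 318 lower under altered rainfall. The median change of the called probes was 1.44 log2 units among those that rose and -1.60 among those that fell, and changes beyond 2 log2 units were found for 42 probes that rose and 94 that fell. An unadjusted p under 0.05 was reached by 1396 probes, where 319 would be expected without any difference. Among the 505 tested probes with a gene symbol (373 genes), 60 passed, 19 higher and 41 lower.

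The 12 largest falls with a gene symbol ran from 3.75-fold to 11.1-fold. LOC542279 (probe 11809) fell by 3.48 ± 0.38 (SE) log2 units, from 7.22 ± 0.46 (SD, n = 10) under ambient to 3.75 ± 1.10 (SD, n = 10) under altered rainfall (limma, adjusted p = 3.23e-07), and was lower in all 10 arrays that measured it. LOC541685 (probe 6687) fell by 3.05 ± 0.30 (SE), an 8.28-fold lower level, from 7.99 ± 0.57 (SD, n = 16) to 4.94 ± 1.04 (SD, n = 16), and was lower in 16 of 16 arrays (limma, adjusted p = 2.95e-09). LOC541632 (probe 10340, -3.03) and LOC542368 (probe 4516, -2.91) fell to a similar extent, in 8 of 8 and 14 of 15 arrays. ATP-D (probe 4774) fell by 2.28 ± 0.41 (SE) log2 units and was lower in 15 of 16 arrays (limma, adjusted p = 0.0001). The change was -2.55 for LOC542581 (probe 4464), -2.11 for LOC542500 (probe 4362) and -1.91 for LOC732841 (probe 2160). The other 2 tested probes of LOC542581 differed by 0.33 (probe 1348) and 0.26 (probe 5780) and did not pass (adjusted p = 0.63 and 0.65). Both probes of LOC542716 fell (-2.17 for probe 9183 and -2.08 for probe 4343), each in 15 of 16 arrays. LOC542370 (probe 6040, -1.99) and LOC541622 (probe 5833, -1.97) completed the 12 largest falls, and the second probe of each gene also fell (-1.36 for probe 11974 and -1.37 for probe 9506). With a floor at the 5th percentile of intensities the fall of LOC542279 was 6.01-fold and that of LOC541632 4.88-fold, against 11.1-fold and 8.15-fold. With loess LOC541632 changed by -2.11 and LOC542581 by -1.68. The call of LOC541632 was lost with within-array loess (adjusted p = 0.11), that of LOC542370 with loess (0.099), the replicate block (0.072), median centring (0.075) and without number 13 (0.058), and that of LOC541622 with loess (0.064) and without number 7 (0.057), 8 (0.058), 9 (0.0501) or 15 (0.061). Without numbers 7, 9 and 19 together neither LOC541622 (0.16) nor LOC542370 (0.06) passed. Without normalization LOC542370 (0.26), LOC541622 (0.098), LOC542500 (0.088) and LOC732841 (0.09) did not pass, and the fall was 2.59-fold instead of 4.31-fold for LOC542500 and 2.37-fold instead of 3.98-fold for LOC542370. With sample weights LOC542370 changed by -2.70.

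**Figure D1:**
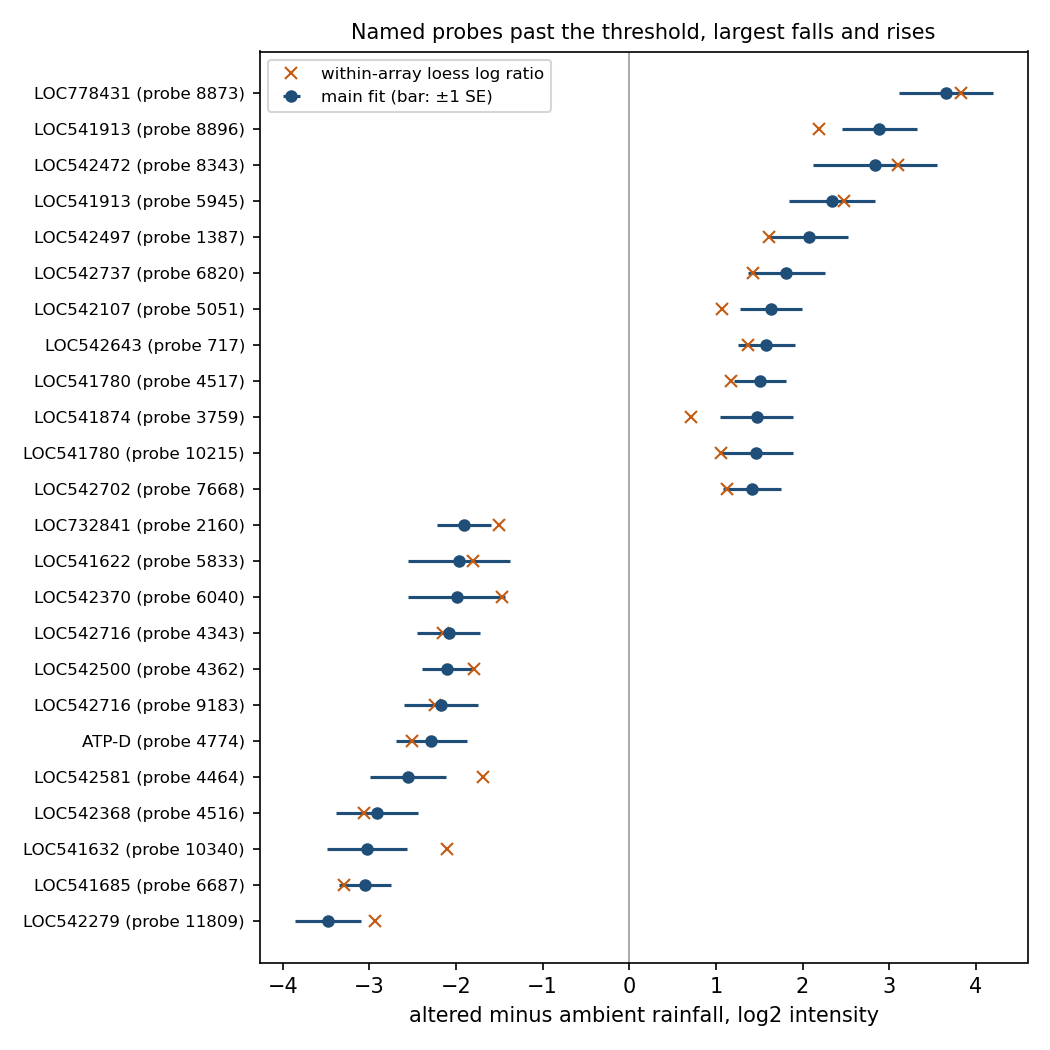
Change of the 24 named probes with the largest rises and falls past the threshold, as altered minus ambient rainfall in log2 intensity (x axis), with 1 row per probe. Points with bars give the fit on quantile-normalized values ± 1 SE and crosses the mean within-array loess log ratio. Each cross lies on the same side of 0 as its point.

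The largest rise with a gene symbol was that of LOC778431 (probe 8873), which rose by 3.65 ± 0.54 (SE) log2 units, from 3.78 ± 1.91 (SD, n = 10) to 7.43 ± 1.18 (SD, n = 14), a 12.6-fold higher level, and was higher in 9 of the 10 arrays with both values (limma, adjusted p = 1.12e-05). Its ambient values lay at the dim end, and the rise was 6.40-fold with a floor at the 5th percentile and 19.6-fold on log2(value + 1). Both probes of LOC541913 rose, by 2.88 ± 0.43 (probe 8896, higher in 13 of 14 arrays) and 2.34 ± 0.50 (SE; probe 5945, higher in 11 of 13). For probe 8896 the rise was 2.05 with the floor and 2.19 with loess. LOC542497 (probe 1387) rose by 2.07, LOC542737 (probe 6820) by 1.81, LOC542107 (probe 5051) by 1.64, LOC542643 (probe 717) by 1.58 and LOC542702 (probe 7668) by 1.41. LOC542737 was the most intense of these, at 8.24 ± 1.79 (SD, n = 16) under ambient and 10.05 ± 0.85 (SD, n = 16) under altered rainfall. The 2 probes of LOC541780 rose by 1.51 (probe 4517) and 1.46 (probe 10215). LOC542472 (probe 8343) rose by 2.84 ± 0.72 (SE), with only 8 values per group, and LOC541874 (probe 3759) by 1.47. The other tested probe of LOC541874, 5708, differed by -0.35 (adjusted p = 0.59), and that of LOC542497, 2286, by 0.70 (adjusted p = 0.26). With the replicate block the calls of LOC542472 (adjusted p = 0.097), LOC541874 (0.068) and probe 10215 of LOC541780 (0.078) were lost, as they were with loess (0.085, 0.20 and 0.15). LOC542737 (0.12), LOC542702 (0.073) and probe 10215 (0.11) did not pass with median centring, nor LOC542107 (0.06) and probe 10215 (0.086) without normalization. That of LOC541874 was also lost without number 9 (0.066) or 17 (0.056), without numbers 7, 9 and 19 together (0.07) and with sample weights (0.057), and that of probe 10215 without number 2 (0.076), 6 (0.077), 11 (0.096) or 18 (0.054) and with the floor (0.052). LOC542472 did not pass with sample weights (0.056). The rise of LOC541874, 2.77-fold, was 1.64-fold with loess and 4.45-fold without normalization. That of LOC542737 was 1.22 log2 units without numbers 7, 9 and 19.

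Chlorophyll a/b-binding proteins hold the pigments of the light-harvesting antenna. Cab-m7, the only gene of that list that a symbol identified, had 1 intense probe that fell and 1 dimmer probe that did not pass the test. Probe 4707 fell by 0.88 ± 0.24 (SE) log2 units, from 12.76 ± 0.47 (SD, n = 16) to 11.88 ± 0.63 (SD, n = 16), a 1.84-fold lower level that was seen in 14 of 16 arrays (limma, adjusted p = 0.012 over all probes). Probe 3766 differed by -0.15 ± 0.35 (SE; limma, adjusted p = 0.85), and by 0.66 without normalization (adjusted p = 0.48). Adjusted over the list alone, 1 of these 2 probes passed (0.0013). Without numbers 7, 9 and 19, whose arrays had few spots or nearly uncorrelated channels, the change of probe 4707 was -0.64 and did not pass (adjusted p = 0.068), nor did it pass without normalization (-0.89, adjusted p = 0.21). With median centring its fall was larger (-1.53, 2.89-fold) and passed (adjusted p = 0.0021). The Hsp70-family gene hsp70-4, a chaperone gene of the heat shock response, differed by 0.94 ± 0.48 (SE) and was higher in 14 of 16 arrays. It did not pass over all probes (limma, adjusted p = 0.24), and it did pass with the replicate block (adjusted p = 0.044). It was the only tested probe of its list, so the list alone leaves the unadjusted value (limma, p = 0.054). With loess (0.86, limma, adjusted p = 0.076) and with median centring (0.42, limma, adjusted p = 0.75) hsp70-4 did not pass. Without numbers 7, 9 and 19 its difference was 0.58 and did not pass (limma, adjusted p = 0.34).

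**Figure D2:**
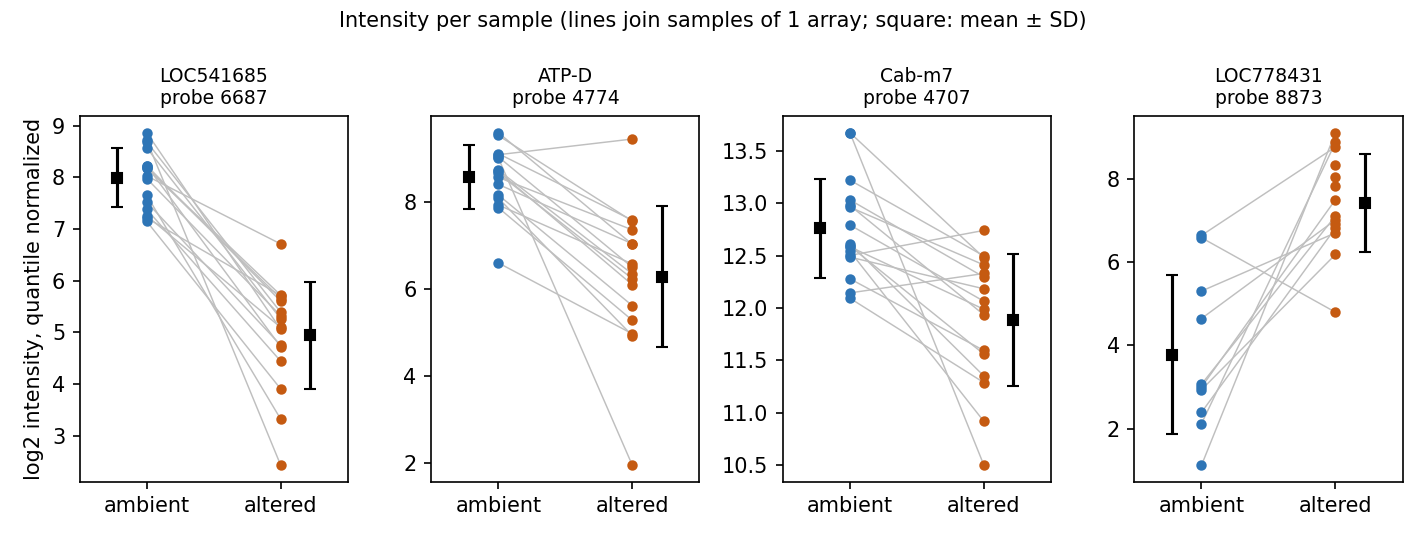
Normalized log2 intensity (y axis) of LOC541685, ATP-D, Cab-m7 (probe 4707) and LOC778431 in each ambient and altered sample. Grey lines join the 2 samples of 1 array, and squares with bars give the group mean ± SD. LOC541685 was lower under altered rainfall in 16 of 16 arrays and LOC778431 higher in 9 of 10.

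Of the 31 tested probes (23 genes) whose symbol is more than a locus number, 3 passed the test: ATP-D, probe 4707 of Cab-m7 and probe 5089 of MPK4, a mitogen-activated protein kinase gene of stress signalling. MPK4 fell by 1.86 ± 0.41 (SE) at that probe (limma, adjusted p = 0.0026, and 0.053 with loess). Its other probe, 398, differed by 0.35 ± 0.49 (SE) in the main fit (limma, adjusted p = 0.73) and by -0.45 with loess (limma, adjusted p = 0.65). The genes pgr5, of cyclic electron flow, and lls1, of chlorophyll breakdown, differed by -0.63 ± 0.41 and 0.91 ± 0.54 (SE) and did not pass. The oxophytodienoate reductase genes opr5 and opr8 differed by -0.09 ± 0.59 and 0.56 ± 0.53 (SE) and did not pass. With loess opr8 differed by -0.15. The 5 probes of the alpha-tubulin gene tua4 ranged from -0.05 to 0.70, and none passed. Probe 181 of tua4 (0.70 ± 0.26, SE; higher in 14 of 15 arrays; limma, adjusted p = 0.092) did pass with the replicate block (adjusted p = 0.042) and with loess (0.046). Genes of chromatin, the histone deacetylase gene HDA108 (0.35 ± 0.42, SE) and the methyl-CpG-binding domain genes mbd101 (0.57 ± 0.43, SE) and mbd109 (-0.17 ± 0.43, SE), did not pass. Among intense probes, the change was 0.03 ± 0.31 (SE) for TCTP and 0.21 ± 0.28 (SE) for the lipid transfer gene PLTP.

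Most called probes carried no gene symbol. Of these, probe 9021 rose by 4.89 ± 0.46 (SE) log2 units and probe 4406 by 3.90 ± 0.49 (SE), each higher in every array that measured both samples (9 and 12). Their ambient values lay at the dim end. The rise of probe 9021 was 10.9-fold with the floor and 19.5-fold with median centring, against 29.7-fold. That of probe 4406 was 7.40-fold with the floor, 6.23-fold with loess (adjusted p = 0.030) and 8.94-fold with sample weights, against 14.9-fold. Probe 6559 fell by 3.22 ± 0.36 (SE), lower in 13 of 13 arrays, and probe 12059 fell by 2.67 ± 0.32 (SE), lower in 16 of 16.

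The direction of these changes tended to be shared across arrays. Of the 2518 probes measured in both channels of at least 14 arrays, 286 were called. Of the 2518, 62 differed in the same direction in every array, where 0.17 would be expected by chance. Among the 286 called probes, 50 did so. Log ratios of altered over ambient, after within-array loess, correlated across probes with a mean r of 0.24 between arrays, and 109 of 120 pairs of arrays had r above 0 (probes are not independent replicates). All 11 pairs below 0 included number 10, whose mean r with the other arrays was -0.03. The channels of number 10 correlated at r = 0.68. The highest mean r, 0.42, was that of number 7, which had the fewest spots (1833) and channels correlated at r = -0.31. For numbers 7 and 10, mean r with the other arrays therefore did not follow the correlation between the channels.

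**Figure D3:**
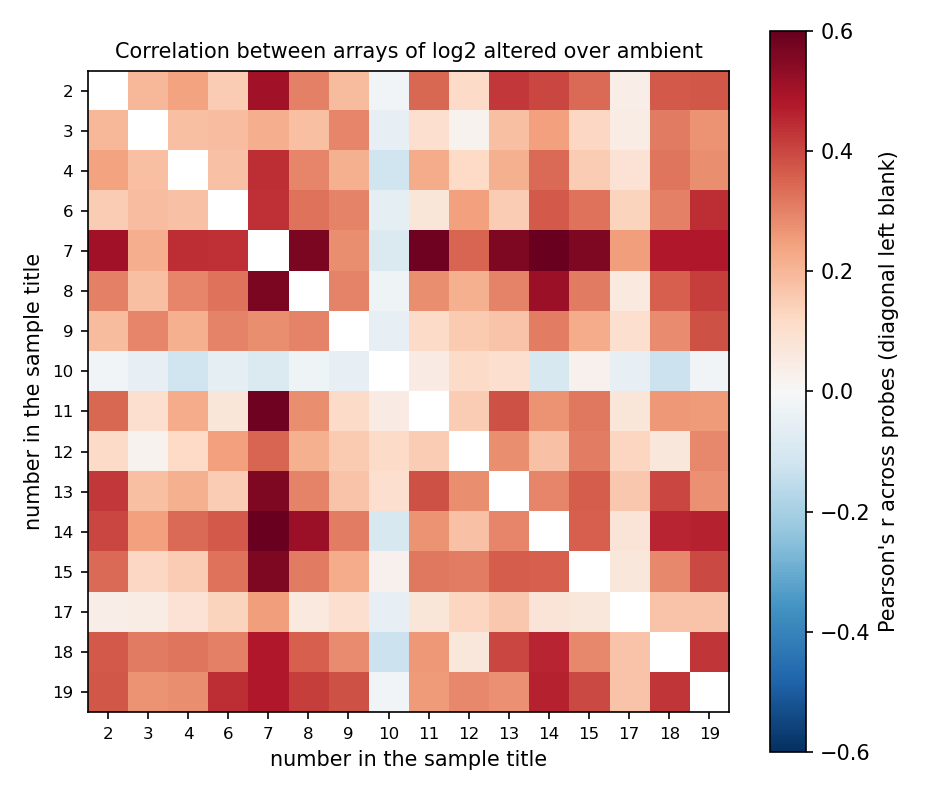
Pearson's r across probes between arrays of the loess-normalized log2 ratio of altered over ambient rainfall, with arrays named on both axes by the number in the sample titles. Colour gives r from -0.6 to 0.6, and only number 10 has values below 0, down to -0.13.

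The replicate block called 588 probes and within-array loess 543, and 441 and 358 of these were among the 576. All 576 had the same direction with loess. The loess ratios came from the same intensities, and the probes were selected for their change (546 of the 576 beyond 1 log2 unit). Their direction with loess is therefore not an independent check. With the block all 576 also kept their direction, but there the direction was fixed in advance wherever both channels had a value. The fits with and without the block then give the same change. In all 3 fits 342 probes passed (132 higher, 210 lower). The split between rises and falls depended on scaling: 44.8% of calls were rises with quantile normalization, 37.2% with loess, 32.8% with median centring and 75.5% without normalization, where the median change of all probes was 0.57 against 0.10, 0.01 and -0.03 for quantile, loess and median centring.

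Within the 3 sets of samples that share a wording of the description, the same comparison called 304 probes in the set of 8 arrays (numbers 11 to 19), 10 in the 4 arrays numbered 2 to 6, and 0 in the 4 arrays numbered 7 to 10 (limma; 561 probes there had an unadjusted p under 0.05). The sets differed in size and the last includes numbers 7, 9 and 10. Of the 304 probes, 296 were also tested in the 16 samples outside that set, and 278 of them changed in the same direction there, 62 past the threshold. All 10 probes called in numbers 2 to 6 had the same direction in the remaining samples, and 9 passed there. Changes in the 8 arrays and in the remaining 8 correlated at r = 0.58 over 5568 probes.

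A difference in the rainfall effect between the 3 sets was found for 2 of 5782 probes (moderated F-test in limma, adjusted p = 0.0097 for probe 1084 and 0.028 for probe 4928, both unnamed and given here after their values were seen). With the replicate block, 0 probes passed (264 at an unadjusted p under 0.05, against 309 without the block).

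A difference in variability between samples under altered and ambient rainfall was not detected. The root mean square deviation from the group mean was 0.98 ± 0.39 (SD, n = 16) log2 units under altered and 0.89 ± 0.39 (SD, n = 16) under ambient rainfall, a difference of 0.089 (two-sided permutation test, p = 0.54). Exchanging samples only within arrays gave p = 0.16 (exact, two-sided), with the altered sample higher in 9 of 16 arrays. With median centring the difference was -0.085 (permutation p = 0.66; exact within arrays 0.56).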

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

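The rainfall effect differed between the 3 sets of samples, by the interaction test, for 2 probes. Altered minus ambient was 1.86, -3.16 and 4.20 log2 units for probe 1084 in numbers 2 to 6, 7 to 10 and 11 to 19, and -1.07, -1.54 and 4.02 for probe 4928. Among 50 assignments of the 16 numbers to sets of the same sizes, the real one included, 18 gave at least 2 probes and the highest other gave 8, so chance cannot be excluded. No biological explanation was tested, because the labels do not say what the sets are.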

How the results depend on the processing

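The count of 576 called probes stayed within 1.5 times under the replicate block (588, of which 441 were among the 576), the block as a random effect, the covariate for the 3 sets, median centring, looser or dim-spot filters, log2(value + 1), the floor, sample weights, the moderation with a trend and both loess fits. It lay between 456 and 619 when each number was left out (rises between 43.0% and 47.5%), and at 480 without numbers 7, 9 and 19. It was 343 without normalization, 131 among the 894 probes measured in all samples (fewer were tested), 10, 0 and 304 within the sets of 4, 4 and 8 arrays (fewer samples), and 1396 at an unadjusted p under 0.05. The share of rises, 44.8% in the main setting, was 75.5% without normalization, 32.8% with median centring and 30.3% with that and the replicate block, 37.2% with loess, 39.5% with loess and the wider channel as covariate, 29.0% among probes measured in all samples, 40.0% without the dimmest 25% of probes, and 30.0% and 35.9% within numbers 2 to 6 and 11 to 19; the cause was not tested. The loess fits, the exchange within arrays, median centring with the block and the fit without numbers 7, 9 and 19 were chosen after seeing the data; quantile normalization as an alternative is the main setting itself, and list tests could not be run with 2 matched symbols. The difference in spread turned to -0.085 with median centring (neither passed, also when samples were exchanged only within arrays), and the 2 interaction probes became 0 with the replicate block. Of 25 called probes (the 24 with the largest named rises and falls and probe 4707 of Cab-m7), 21 passed with the replicate block, 19 with loess and 19 with both. The named probes followed through the settings were 27, these 25 with probe 3766 of Cab-m7 and hsp70-4. Among the 27, direction turned in 4 of the fits. Probe 10215 of LOC541780 turned within numbers 7 to 10 (-0.18). Probe 3766 of Cab-m7, which did not pass, turned within numbers 2 to 6 (0.038), without normalization (0.66) and without number 12 (0.023, and -0.27 to 0.023 over the numbers left out). Outside the 27, probes also turned with loess, such as opr8 (-0.15), probe 398 of MPK4 (-0.45) and TCTP (-0.0027), none of which passed. Signal over background is unknown here, which limits most the changes where 1 group lies at the dim end.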

Other observations

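Apart from the tests on other splits of the samples, the tests in this part were chosen after the result was seen. Genes represented by several probes gave a view of the data that does not rest on single spots. Of 102 genes with at least 2 tested probes, 10 had 2 called probes, and in all 10 both moved in the same direction. They were LOC541780 and LOC541913, which rose, and LOC541622, LOC542212, LOC542227, LOC542370, LOC542603, LOC542605, LOC542627 and LOC542716, which fell. No gene had called probes in both directions. Some of these calls depended on the fit. Probe 10215 of LOC541780 and probe 6040 of LOC542370 did not pass with the replicate block or with loess, nor did probe 5833 of LOC541622 with loess. Both probes of LOC541913 and of LOC542716 passed in both fits. The changes were -1.81 and -1.48 log2 units for LOC542603, -1.53 and -1.23 for LOC542627, and -1.65 and -1.24 for LOC542227. Among the genes with exactly 1 called probe, LOC100037824, LOC541874, LOC542581, LOC732827 and MPK4 had another probe on the opposite side of 0. The rest of that group had all probes on the same side. Of the 78 genes with no called probe, 52 had all probes on the same side of 0. The others had probes on both sides, such as the 6 probes of LOC542434 (-0.06 to 1.40).

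Over the 176 pairs of probes of 1 gene, the mean absolute difference in change was 0.45 log2 units, against a median of 0.83 and a minimum of 0.65 in 10000 random sets of pairs of named probes, and 73.9% of pairs had the same sign. Genes with many probes gave more of the pairs, and the random sets also drew on genes with 1 tested probe. The random sets are therefore not a matched reference. A smaller difference within genes would follow from a difference between the groups in the transcript, but without a matched reference it does not decide this. It does not exclude a bias that acts on the sequence, which probes of 1 gene share. The changes compared came from the main fit without loess, so an intensity-dependent difference between the channels is not excluded here either.

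The shared log ratios between arrays may come from rainfall or from a channel bias. The sample titles give no dye, but the wider of the 2 log2 intensity distributions was the altered channel on 7 arrays and the ambient channel on 9. Mean log ratios of these 2 sets of arrays correlated at r = 0.39 across 6382 probes, and between 0.32 and 0.42 with any array left out. A bias that follows the wider channel, as the only cause, predicts r below 0. Much of the correlation came from the called probes, which were selected on the same arrays. Among the other probes r was 0.09, where that selection lowers it by an amount that was not measured. Such a bias beside a shared difference could also leave r above 0, so r alone does not exclude it. A term for the wider channel itself passed for 4 probes. Between the arrays with the altered channel multiplied by a factor and those with the ambient channel multiplied r was 0.48, but this does not test that step, since a factor adds 1 constant to all log ratios of an array and cannot change r. After loess 62.2% of the called probes passed, which argues against an intensity-dependent difference as the whole cause. Whether 1 group carried the same dye on every array cannot be told apart from rainfall with these labels (mean r between arrays 0.24), so a dye bias of single genes stays open beside rainfall and any difference in the handling of the 2 groups.

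The count of 576 probes was reached by 1 of 100 splits of the 32 samples into 2 groups of 16, the real one, and the highest of the others gave 2. Among 100 splits that exchanged the samples only within arrays, again 1 gave as many, and the highest of the others gave 55. Chance is therefore an unlikely source of the count in both, though 100 splits cannot show a share below 1 in 100.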
